A study of Drosophila melanogaster with 2 samples.

How the data were processed

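Chromatin immunoprecipitation followed by sequencing was carried out on whole embryos of a transgenic fly line that carries a C-terminal GFP fusion of TFAM, with an antibody against GFP, per the sample descriptions. The antibody field of the labels names TFAM instead, and the descriptions were followed. There were 2 samples, biological replicates 3 and 4 of 1 group, each from its own biosample. Sonicated fragments of 200 to 800 bp were used, per the labels. The files used hold peaks on the builds dm6 and dm3. The authors made a list of peaks and background regions for each replicate separately, with a control alignment, and once more on the alignments of both replicates together with the control, per the deposited descriptions of the files. These lists were the input to the reproducibility threshold and are not peaks at a fixed error rate. From these 3 lists the authors derived a list of peaks that passed a threshold on the irreproducible discovery rate, a measure of rank reproducibility between replicates. The aligner, the peak caller and their settings are not given in the sources used here.

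Each deposited peak has a value on an open-ended scale, here called a score, that the authors' peak caller assigned against the control, and its scale differs between lists. The deposited lists also give the −log10 of a q-value for each peak, used only to separate regions with a q-value of 0.05 or less in alternatives added after seeing the data. The score was used to rank peaks within a list, to describe them and to compare promoter peaks with others. No read counts are in the lists, so the depth is unknown, and no interval that needs it is given. The Wilson intervals (95%) cover the counting of peaks or genes only. No control or untagged sample was used here.

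Chromosome names and lengths of the reference FASTA (RefSeq, Release 6 of the fly genome) were compared with the dm6 lists, and all peak ends lay within the chromosome lengths. Genes came from the Ensembl 115 annotation (BDGP6.54), without transposable element insertions. No genome of the dm3 build was used here, so the dm3 lists gave counts, values and shares only, and no coordinates were converted. All positions are dm6 and counted from 1.

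The tests, the gene lists, the motifs, the alternatives and the rule for named genes were fixed before the data were examined. A promoter peak is one whose summit lies within 500 bp of any annotated transcription start site. Summits were placed at random 1000 times on the same chromosomes, outside runs of N, to give the random share of promoters (one-sided permutation p) and of the annotation classes (two-sided, in the order promoter, 5' UTR, coding sequence, 3' UTR, other exon, intron, intergenic). Many mitochondrial genes are short, so most mitochondrial summits count as promoter peaks, and the promoter share of nuclear peaks was computed as well. Peak numbers per chromosome were compared with assembled length by exact binomial tests. Gene lists were compared with all other protein-coding genes on 2L, 2R, 3L, 3R, 4 and X (all genes for the histone and transfer RNA lists) by Fisher's exact test, as were motifs within 100 bp of the summit, against pooled-list regions, background included, that overlap no thresholded peak. Values at promoters and elsewhere, and the rank correlation between replicates, were tested with 100000 permutations. Benjamini-Hochberg adjustment was applied within each family (7 classes, 9 sequence classes, 16 lists, 10 motifs) with a threshold of 0.05.

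The genes named are those with the nearest protein-coding start site to the 25 thresholded peaks of highest value, TFAM, the 3 members of each list with the highest promoter peak, and the 5 highest peaks outside promoters. On the mitochondrial genome, peaks are named by the gene that contains the summit. Because mitochondrial peaks filled 22 of the 25 places, the 25 highest nuclear peaks are named too, and the 5 peaks outside promoters were taken among nuclear peaks; both choices were made after the values had been seen. Symbols were looked up in the annotation, and the pair-rule gene h was found there as hry.

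The tests were tried on simulated peaks, 1268 on the nuclear chromosomes. With summits placed at random, the promoter test gave p under 0.05 in 4% of 100 draws, the class test in 3.14% of 700, the promoter value test in 3% of 100, and 0.31% of 320 list tests passed the adjusted threshold. With 300 summits planted at start sites, the mean promoter share was 34.0% where 34.1% was expected, and 20 of 20 draws passed. With 40 ribosomal genes planted, 20 of 20 draws passed. In the comparison of values at promoters and elsewhere, a planted 1.2-fold shift of the value passed in 20 of 20. This does not show power for smaller shifts, such as the one observed (medians of 138 and 125.0). The motif check used strings of random bases, not peaks: DRE planted in 30 of 300 windows passed in 20 of 20. It does not show power for smaller differences in A+T-rich windows. Random summits were drawn by the same procedure as the placements of the promoter and class tests. Their rates thus check the computation only, not the effect of clustering among real peaks.

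Alternatives covered the promoter window (200 and 1000 bp), the motif window (50 bp), the 645 thresholded peaks with the highest values, each replicate left out (the other replicate's list cut to its 1290 highest peaks), other definitions of overlap, other backgrounds, comparison peaks matched on GC content in bins of 2 points, the wider TFAM locus and the dm3 lists. Results with nuclear peaks alone, with regions of a q-value of 0.05 or less, without a promoter class, and the direct comparison of mitochondrial summits were added after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Matplotlib 3.10.9 and BLAST 2.17.0 were used.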

Results

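The data describe where TFAM, tagged with GFP at its C terminus, was recovered on DNA in whole fruit fly embryos (Drosophila melanogaster). TFAM is the HMG-box protein that packages mitochondrial DNA. Chromatin from embryos of both sexes, aged 0 to 16 h, was sheared to fragments of 200 to 800 bp and precipitated. The sample descriptions name an antibody against GFP, which is followed here, while the antibody field of the labels names TFAM. The 2 samples form 1 group and are biological replicates from separate biosamples, numbered 3 and 4. The values are peak lists, which hold no read counts, so the depth of each library is unknown. Each peak carries a value set by the authors' peak caller. It is used here to describe and rank peaks within a list and to compare promoter peaks with others. On the dm6 build, the list of replicate 3 held 13396 regions, that of replicate 4 held 13455, the list called on both replicates together (the pooled list) held 9598, and the list kept by the authors' reproducibility threshold (the thresholded list) held 1290 peaks. The first 3 lists were deposited as peaks together with background, with q-values of up to 0.96. A q-value of 0.05 or less was held by 3196 regions in replicate 3, 1717 in replicate 4, 2476 in the pooled list and all 1290 thresholded peaks. Comparisons limited to such regions were added after seeing the data. No control sample was analysed here, so no comparison between groups was made. Peaks and genes are not independent replicates, and every p-value below describes these lists only.

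The first question was whether thresholded peaks lay on the mitochondrial genome. They did: 22 of the 1290 thresholded summits lay on the 19524 bp mitochondrial genome, in 13 separate regions that together covered 8658 bp. The highest stood in mt:ND4, a subunit of respiratory complex I (M 8447 to 9032, coding sequence, peak value 22009). Next came mt:CoI and mt:CoII, which encode subunits of cytochrome c oxidase (M 1283 to 3122, value 21068, and M 3253 to 3867, value 19749), and mt:Cyt-b of complex III (M 10433 to 11594, value 18424). By comparison, the highest nuclear peak had a value of 837 and the median nuclear peak 129.8. In all, 20 of the 22 mitochondrial peaks exceeded every nuclear one in dm6. In the thresholded list deposited on the older dm3 build this held for 2 of 4 mitochondrial peaks, with values of 1479, 1168, 576 and 98.9 against a nuclear maximum of 838, and these covered 1017 bp.

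The mitochondrial summits were spread over the coding part of the molecule. Of the 22, 17 lay in 7 of the 13 protein-coding genes, with 4 in mt:CoI, 4 in mt:CoIII, 3 in mt:Cyt-b, 2 in mt:ND1, 2 in mt:ND5 and 1 each in mt:CoII and mt:ND4. The ribosomal RNA genes mt:lrRNA and mt:srRNA held 4 summits, with values of 3266 to 7664, and the remaining summit lay in mt:tRNA:Ala-TGC (M 5891 to 6232, value 4790). Peaks covered 58.0% of the coding part, including the full length of mt:CoI and mt:CoIII. None of mt:ND2, mt:ND4L and mt:ATPase8 was covered. No base of the A+T-rich control region (M 14917 to 19524), where replication starts, lay under a thresholded peak.

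The mitochondrial summits of the replicates were compared directly, a test chosen after seeing the data. Of the 22 replicate 3 summits, 17 lay within 100 bp of a replicate 4 summit, with a median distance of 11 bp and a maximum of 257 bp. Of 22 summits placed at random inside the replicate 3 peaks, 10.7 ± 2.35 (SD, 1000 placements) lay within 100 bp. Their median distance was 106.7 bp ± 26.5 (SD, one-sided permutation p for the median = 0.001, the smallest possible here). The random summits were drawn evenly over all covered bases, not peak by peak or near peak centres. Regions shared by the replicates can bring summits closer than that, so this p-value does not show agreement of summits beyond shared regions. The highest mitochondrial peak exceeded the highest nuclear peak 24.3-fold in replicate 3 (8823 against 362) and 28.7-fold in replicate 4 (13620 against 474) on dm6. On dm3 the ratio was 1.78 in replicate 3 (643 against 361) and 2.03 in replicate 4 (965 against 474). Against its share of the assembled length, the mitochondrial genome held 125-fold more thresholded peaks than expected (exact binomial test, two-sided, adjusted p = 1.5e-37 over 9 sequence classes). That share counts each sequence once. The number of mitochondrial genome copies per cell was not known here, and no untagged line was analysed. The excess and the value ratios are therefore not a measure of binding by the tagged protein. All 22 mitochondrial regions of the pooled list were kept in the thresholded list.

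**Figure D1:**
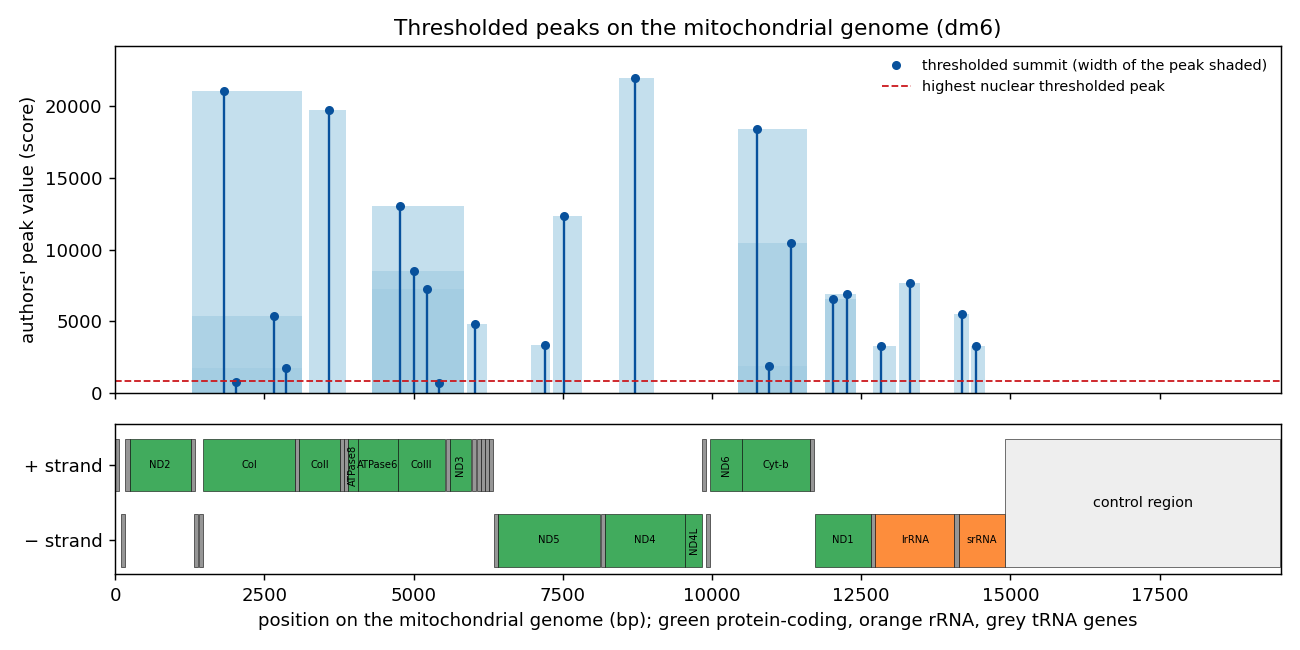
Map of the mitochondrial genome in dm6, with position in bp on the horizontal axis. The upper panel gives the authors' peak value (score) of the 22 thresholded summits, with each peak's extent shaded and a dashed line at 837, the highest nuclear peak; the lower panel shows the genes by strand and the control region, which holds no peak.

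On the nuclear chromosomes the highest thresholded peak lay 43 bp upstream of the start site of Ugalt, which encodes a Golgi UDP-galactose transporter (X 2703744 to 2704033, value 837). It was followed by peaks in the promoters of px (2R 22514154 to 22514418, value 810) and CG14100 (3L 19590492 to 19590731, value 723). The 25 highest nuclear peaks, named after their values had been seen because 22 of the 25 highest peaks overall were mitochondrial, had values from 437 to 837. Of these, 15 lay at promoters. They included the Polycomb group gene ph-p (value 656), the mitochondrial ribosomal protein genes mRpS10 (594) and mRpL41 (486), PNPase, which encodes a mitochondrial exoribonuclease (563), and Chro, a chromodomain protein gene (523). The other promoter peaks stood nearest to hll (618; 2918 bp from its protein-coding start site, at the promoter of another transcript), CenG1A (546), CG1888 (543), CG13921 (487), Tina-1 (459), CG18549 (450.4) and Fkbp14 (437).

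The 5 highest peaks outside promoters were all intronic. The first lay in an intron of ush, a transcriptional cofactor gene, with cbt as the nearest start site (2L 480943 to 481224, value 693). The others lay in introns of CG11050 (2L 6612579 to 6612836, value 638), CG32772 (X 4910256 to 4910498, value 563), cno (3R 5215406 to 5215634, value 516) and Lk6 (3R 11760932 to 11761157, value 515). Further introns among the 25 were those of sbb (464), Trl (464), which encodes GAGA factor, and CG9663 (447). The 2 intergenic peaks were nearest to CG31668 (494) and CG13323 (476).

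Promoters held 633 of the 1290 thresholded summits, within 500 bp of an annotated start site. This was 49.1% (95% Wilson interval 46.3 to 51.8), against 14.6% ± 0.98 (SD) over 1000 random placements on the same chromosomes, a 3.37-fold excess (one-sided permutation p = 0.001, the smallest these placements can give). Within 200 bp the share was 31.4%, against 6.71% at random. Among pooled regions that overlapped no thresholded peak, background included, 34.6% lay at promoters (2831 of 8181, 33.6 to 35.6). The odds of a promoter position were 1.82 times higher in the thresholded list (Fisher's exact test, two-sided, p = 5.3e-23), and 1.42 times higher against the 1148 remaining regions with a q-value of 0.05 or less, of which 40.4% lay at promoters (exact p = 1.9e-05). Of the 616 nuclear promoter summits, 515 lay upstream of the nearest start site, 101 downstream, and the median position was -122 bp.

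**Figure D2:**
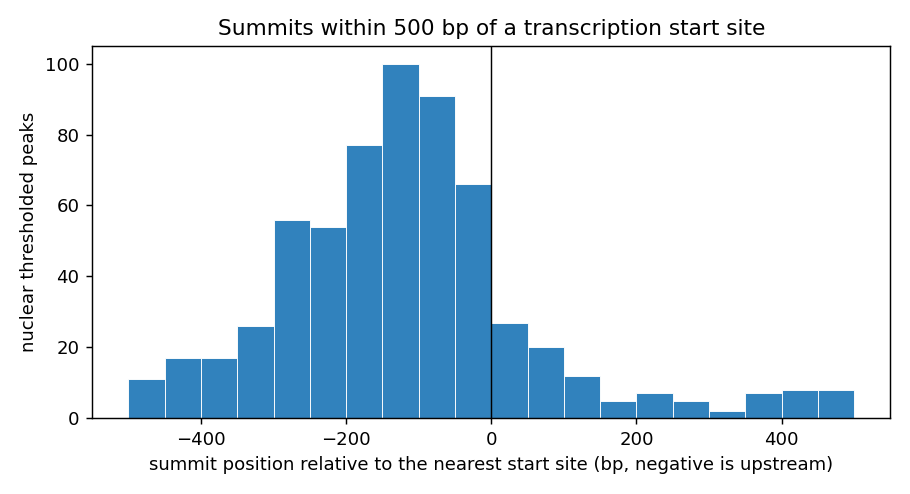
Number of nuclear thresholded peaks (vertical axis) by position of the summit relative to the nearest start site in bins of 50 bp (horizontal axis, negative values upstream), for the 616 summits within 500 bp. The upstream side holds 515 of them.

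Outside promoters, which were assigned first, few summits lay in coding sequence and 3' UTRs. Coding sequence held 8 summits (0.62%, against 13.6% ± 0.96 at random) and 3' UTRs held 7 (0.54%, against 4.34% ± 0.57). Intergenic sequence held 156 (12.1%, against 26.8% ± 1.18). These 3 classes fell below random placement (two-sided permutation test, adjusted p = 0.0035 each over 7 classes, the smallest these placements can give here). Without a promoter class, a choice made after seeing the data, coding sequence held 22 summits, 17 of them mitochondrial (1.71% against 17.5% ± 1.05), and 3' UTRs 10 (0.16-fold; adjusted permutation p = 0.0024 each). The promoter summits then counted in the other classes, and introns (1.21-fold), intergenic sequence (1.18-fold) and 5' UTRs (2.34-fold) lay above random placement (adjusted permutation p = 0.0024 each). With promoters assigned first, introns held 464 summits (35.97% against 38.7% ± 1.34, adjusted permutation p = 0.053), which did not pass the threshold. With nuclear peaks alone, a choice made after seeing the data, introns passed it (0.93-fold, adjusted permutation p = 0.045), as they did among the 645 highest peaks (0.83-fold, adjusted p = 0.0028) and without replicate 4 (0.90-fold, adjusted p = 0.011). The 5' UTR (6 summits, 0.61-fold, adjusted permutation p = 0.31) and other exons (16 summits, 1.04-fold, adjusted p = 0.95) did not pass either. With promoters assigned first, fewer summits than at random were left for all other classes together. The low intron and intergenic folds therefore do not show that these classes were avoided.

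**Figure D3:**
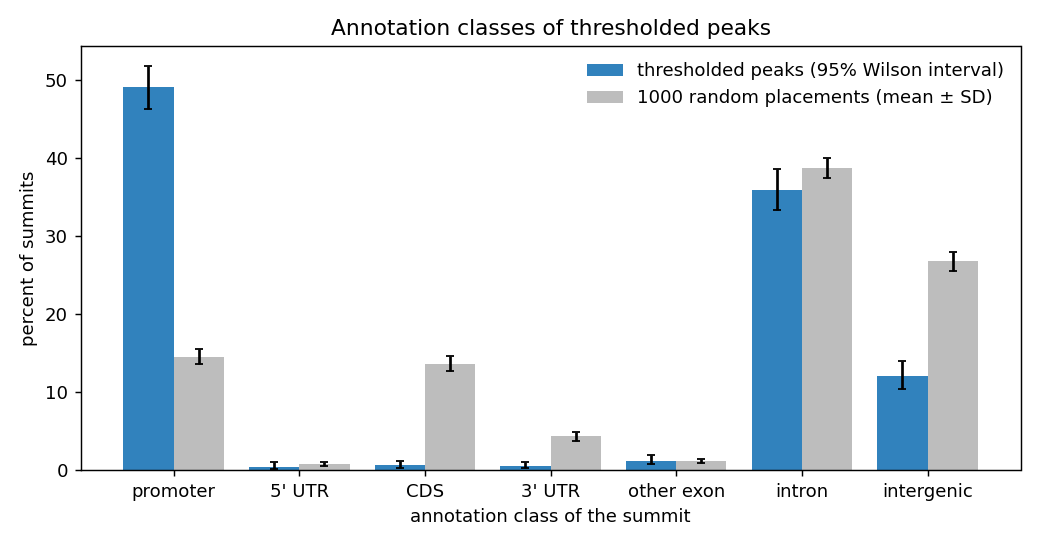
Percent of thresholded summits in each annotation class (blue, with 95% Wilson intervals) and the mean and SD of 1000 random placements (grey). Promoters stand at 49.1% against 14.6%, and coding sequence at 0.62% against 13.6%.

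Peak density on the large chromosome arms and X lay between 8.98 peaks per Mb (2R) and 10.4 (2L). Chromosome 2L held 245 thresholded peaks, 1.15-fold its share of the assembled length (exact binomial test, adjusted p = 0.041), but 1.00-fold its share of the pooled-list regions (adjusted p = 0.97), and it did not pass without replicate 3 (adjusted p = 0.064). Chromosomes 2R (0.99-fold), 3L (1.07-fold), 3R (1.06-fold) and X (1.00-fold) did not pass the threshold, nor did chromosome 4, with 5 peaks (3.76 per Mb, 0.42-fold, adjusted exact p = 0.074). The Y chromosome and the unplaced sequences held no peak (adjusted exact p = 1.3e-13 and 6.8e-22), in the thresholded list or in any other dm6 list. Without replicate 3, chromosome 4 passed (0.33-fold, exact test, adjusted p = 0.030). Whether reads on the Y chromosome and unplaced sequences were kept before peak calling is not given in the sources used here, so the p-values for them do not show absent binding. On dm3, heterochromatin sequences held 42 regions in replicate 3, 25 in replicate 4, 6 in the pooled list and 0 in the thresholded list.

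Genes of the cytosolic ribosome had thresholded peaks at their promoters far more often than other genes. Of 92 such genes, 46 were occupied (50%, 95% Wilson interval 39.99 to 60.0), against 5.05% of other protein-coding genes (Fisher's exact test, two-sided, odds ratio 18.8, adjusted p = 5.3e-33 over 16 lists). With only genes near a pooled-list summit as background, the shares were 63.0% and 20.3% (odds ratio 6.71, adjusted exact p = 9.4e-14). Where that summit had a q-value of 0.05 or less they were 83.6% and 55.3% (odds ratio 4.13, adjusted exact p = 2.8e-04). The highest values stood at RpS27 (3R 25247417 to 25247609, value 310.4), RpL7 (2L 10200950 to 10201112, value 303) and RpL14 (3L 8600901 to 8600998, value 288). Large subunit genes made up 31 of the occupied genes (of 53) and small subunit genes 15 (of 38), while sta was not occupied. The median value of these peaks was 152, beside 129.8 for nuclear thresholded peaks.

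Nuclear transfer RNA genes were occupied less often than other genes: 3 of 290 (1.03%, 0.35 to 3.00) against 4.57% (adjusted exact p = 0.012). The 3 were tRNA:Tyr-GTA-1-8 (value 241), tRNA:Trp-CCA-2-2 (143) and tRNA:Phe-GAA-1-2 (119.5), and the last shares its peak with RpL17. The call did not pass with only genes near a pooled-list summit as background (adjusted exact p = 0.090, or 0.86 where that summit had a q-value of 0.05 or less), nor among the 645 thresholded peaks with the highest values (adjusted p = 0.20). With these backgrounds far fewer genes were left, and the shares were 6.12% (3 of 49) against 20.7%, and 37.5% (3 of 8) against 56.4%. The number of annotated start sites per gene was not adjusted for.

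Genes that act in mitochondria did not pass the test as groups. Among genes for mitochondrial DNA maintenance and expression, 2 of 15 were occupied, the protease gene Lon (value 246) and mtSSB, the single-stranded DNA binding protein gene (98.4; adjusted exact p = 0.34). Of 73 mitochondrial ribosomal protein genes, 7 were occupied (9.59%, adjusted exact p = 0.30), led by mRpS10 (594), mRpS23 (546) and mRpL41 (486). The mRpS23 peak is the one nearest to CenG1A. Of 91 nuclear genes for oxidative phosphorylation, 2 were occupied, ND-ASHI (134) and ND-MWFE (114; adjusted exact p = 0.39), and the ND-MWFE peak had no counterpart in the replicate 4 list. Counting each peak for its nearest start site only, 0 of the 91 were occupied. Among regulators of mitochondrial and growth genes, 3 of 11 were occupied (27.3%, adjusted exact p = 0.073), namely yki (138), Dref (119) and ERR (96.7). All 3 peaks were nearer to the start site of another gene, so with the nearest start site only 0 of the 11 were occupied, and Dref and RpL13 share 1 peak (2L 9967122 to 9967511).

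No list of developmental regulators or tissue markers passed the test. None of 30 early patterning genes (adjusted exact p = 0.59), 8 Hox genes (adjusted p = 1) or 11 germ line and maternal genes (adjusted p = 1) had a thresholded summit, with upper limits of the Wilson interval of 11.4%, 32.4% and 25.9%. Neural markers (1 of 17, elav, value 281, adjusted exact p = 0.75), muscle markers (2 of 15, sls at 138 and tin at 115, adjusted p = 0.34) and gut, fat body, blood and tracheal markers (1 of 13, fkh, value 185, adjusted p = 0.68) did not pass. Heat shock and chaperone genes were occupied at 3 of 26 (Hsp27, value 297, Hsp83, 253, and lncRNA:Hsromega, 142; adjusted exact p = 0.34), and cell cycle genes at 1 of 27 (RnrS, value 101, adjusted p = 1). None of 115 histone genes was occupied (upper limit 3.23%, adjusted exact p = 0.057). That list passed with a window of 1000 bp (adjusted exact p = 0.011) and without replicate 4 (adjusted p = 0.036). Only 3 of the 115 had a pooled-list summit, background included, near a start site. Regions of any kind were thus rarely called at these genes, so their lack of peaks does not show absent binding. Broadly expressed cytoskeletal and metabolic genes were occupied at 3 of 15, namely Gapdh2 (259.8), RpL32 (222) and eEF1alpha1 (133; adjusted exact p = 0.14). They passed with a window of 1000 bp (adjusted exact p = 0.011) and without replicate 3 (adjusted p = 0.044), and RpL32 is also a member of the ribosomal list.

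**Figure D4:**
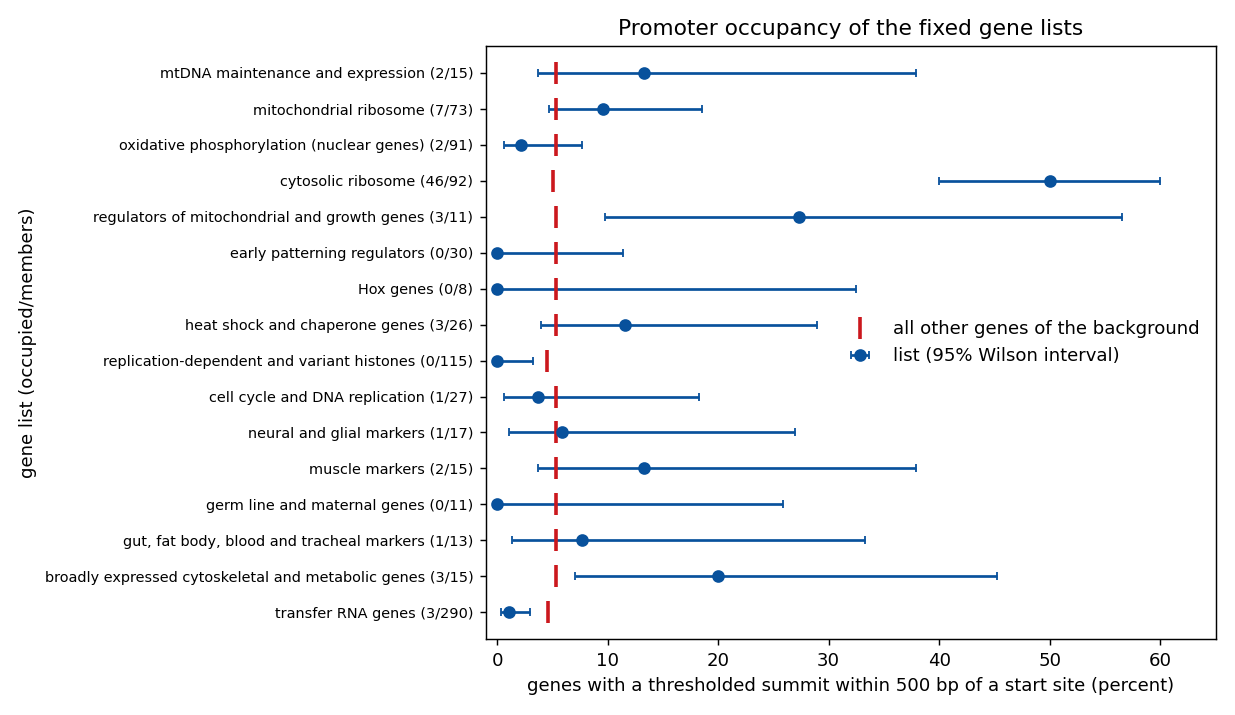
Percent of genes in each of the 16 lists with a thresholded summit within 500 bp of a start site (points, with 95% Wilson intervals), and the percent of all other genes in the background (red ticks). Cytosolic ribosomal genes stand at 50%, against 5.05% of other genes.

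Promoter peaks had slightly higher values than peaks elsewhere. The median was 138 at promoters and 125.0 elsewhere, a difference of 12.8 (permutation test, two-sided, p = 5.3e-04, 633 against 657 peaks). With the value each peak had in replicate 3 the difference was 9.61 (p = 1e-05, the smallest the permutations can give), and with that in replicate 4 it was 3.40 and did not pass (p = 0.076). With nuclear peaks alone it was 9.74 (permutation p = 0.0057), and without replicate 3 it was 4.87 (p = 0.0045).

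Sequence under the thresholded peaks was richer in A and T than under the remaining regions of the pooled list, most of which had q-values above 0.05 (1148 of 8181 did not). Windows of 100 bp on either side of the summit had a mean GC content of 35.99% ± 6.72 (SD), against 41.1% ± 8.76 in all remaining regions and 37.2% ± 7.22 in those with a q-value of 0.05 or less. Of the 10 motifs tested, TATAAA, the TATA box core, was present in 34.8% of thresholded peaks and 25.3% of all remaining regions (Fisher's exact test, two-sided, adjusted p = 1.9e-11), and the repeat CACACACA in 3.95% and 6.20% (adjusted p = 0.0057). Neither difference passed against remaining regions with a q-value of 0.05 or less, where TATAAA was present in 30.3% (adjusted exact p = 0.098) and CACACACA in 5.75% (adjusted p = 0.15). Neither passed against remaining regions matched on GC content, where TATAAA was present in 33.7% (adjusted exact p = 0.74) and CACACACA in 4.26% (adjusted p = 0.85). The motifs of GAGA factor (4.96% and 4.09%), DRE (2.56% and 1.99%), Zelda (1.32% and 1.26%), the E-box (2.48% and 2.42%), core promoter motif 1 (1.09% and 1.22%), NRF1 (0.16% and 0.11%), nuclear receptors (1.01% and 1.85%) and ETS factors (5.89% and 5.02%) did not pass, with adjusted p from 0.097 to 0.85. Without replicate 3, GAGA factor (adjusted exact p = 0.022) and DRE (0.0047) passed and CACACACA did not (0.73), and among promoter peaks the nuclear receptor motif was less frequent (0.0081).

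Replicate lists overlapped far more than random placement gave. Of replicate 3 regions, 46.5% overlapped a replicate 4 region by at least 1 bp (6233 of 13396), against 7.63% ± 0.23 over 100 random placements. The reverse share was 45.1% (6074 of 13455), against 7.42% ± 0.24. Among regions with a q-value of 0.05 or less the shares were 45.3% and 81.4%. Among the 1290 highest peaks of each replicate, 67.6% and 67.0% overlapped. The values of thresholded peaks in the 2 replicates were rank correlated across 1288 peaks (Spearman rho 0.55, permutation p = 1e-05, the smallest possible here), and across the 1266 nuclear ones (rho 0.53). The authors kept these peaks for their reproducibility, so this correlation describes the kept peaks only.

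**Figure D5:**
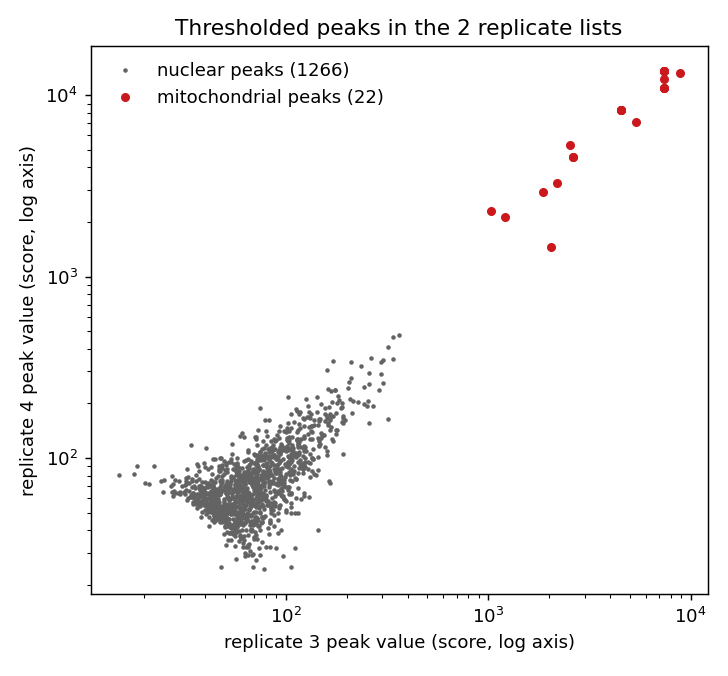
Value of each thresholded peak in the replicate 3 list (horizontal, score, log axis) and the replicate 4 list (vertical, score, log axis), as the highest overlapping peak, so that mitochondrial summits of 1 region (red) share its highest value. Taken singly, 21 of 22 mitochondrial peaks in the replicate 3 list and 20 of 21 in the replicate 4 list exceeded every nuclear peak (grey).

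The TFAM gene itself (3R 20575245 to 20577010) had no thresholded peak within 2 kb. The pooled list held 3 regions there, the highest at 3R 20574681 to 20575070 with a value of 71.4, rank 2036 of 9598 (q = 0.024). Replicate 3 held 3 such regions, none with a q-value of 0.05 or less (highest value 23.3, q = 0.16), and replicate 4 held 4 (highest value 49.2, q = 0.021). Within 10 kb there was 1 thresholded peak (3R 20579832 to 20580221, value 162).

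The dm3 lists were longer than the dm6 lists at every stage. There were 21414 against 13396 regions, background included, for replicate 3 (1.60-fold), 24896 against 13455 for replicate 4 (1.85-fold), 15643 against 9598 in the pooled list (1.63-fold) and 1801 against 1290 in the thresholded list (1.40-fold). Of regions with a q-value of 0.05 or less there were 3480 against 3196 (1.09-fold), 2039 against 1717 (1.19-fold) and 2777 against 2476 (1.12-fold) in the first 3 lists. On 2L, 2R, 3L, 3R, 4 and X the highest thresholded value was nearly equal in the builds (838 in dm3 and 837 in dm6), while the median was 109.9 in dm3 and 129.8 in dm6. The longer dm3 list also reached down to lower values (minimum 77.2, against 92.4 in dm6), so the medians do not compare the same peaks. The share of thresholded peaks on the X chromosome was 16.9% in dm3 and 16.4% in dm6.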

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

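Nuclear peaks alone, regions with a q-value of 0.05 or less and classes without a promoter class were alternatives chosen after seeing the data. Depth is not known from peak lists, so what it limits could not be tested, and the cause of each change below was not tested except where the alternative's construction shows it. The binomial test could not be run on dm3, for which no lengths were used. The promoter share, coding sequence and 3' UTR calls, the cytosolic ribosome and the rank correlation kept their direction and side of the threshold under each alternative run on them. Intergenic sequence did so too except without a promoter class, and the promoter value difference except with replicate 4 values, where it was 3.40 and did not pass (permutation p = 0.076). The mitochondrial excess over length was 119-fold without replicate 3 and 125-fold without replicate 4. Its folds against the pooled list and among the 645 highest peaks are fixed by list length, since all 22 peaks stay, and test nothing.

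With dm3, the lists held 21414 (replicate 3), 24896 (replicate 4) and 15643 (pooled) peaks, the mitochondrial genome 4 thresholded peaks (2 above every nuclear peak), and the overlaps were 48.5% and 41.6%. The overlaps, for replicate 3 and replicate 4 in turn, were 39.4% and 38.8% with reciprocal overlap (at least 50% of each peak), 32.4% and 32.2% with summits within 100 bp, and 67.6% and 67.0% among the top peaks. Within 10 kb of TFAM there was 1 thresholded peak. With nuclear peaks alone, introns passed at 0.93-fold.

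With a q-value of 0.05 or less, the lists held 3196 (replicate 3), 1717 (replicate 4) and 2476 (pooled) regions, the overlaps were 45.3% and 81.4%, the dm3 to dm6 ratio for replicate 4 was 1.19, and 0 motifs were more and 0 less frequent. Against the share of such pooled regions, 2L (0.99-fold), 3R (0.96-fold) and X (1.03-fold) turned without passing. With genes near such a summit as background, 0 lists were occupied less often (transfer RNA genes -1.02), and cell cycle genes (-1.12) and gut and other markers (-0.38) turned. Without a promoter class, whose summits then fall in other classes, 5' UTRs (2.34-fold), introns (1.21-fold) and intergenic sequence (1.18-fold) turned and other exons passed (1.49-fold).

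In the 645 peaks with the highest values, introns passed at 0.83-fold, other exons stood at 0.79-fold and 3L at 0.99-fold, no list was occupied less often (0; transfer RNA genes at a log2 odds of -1.57), cell cycle genes stood at -0.73, germ line genes at 0.53 and Zelda at -0.37, and 0 motifs were less frequent. Against the share of all pooled regions, 2L no longer passed (1.00-fold), and 3L (0.92-fold), 3R (0.98-fold) and X (1.13-fold) turned without passing. With a 1000 bp window, 2 lists were occupied more often (adding broadly expressed genes, log2 odds 2.93) and 2 less often (adding histones, -3.84), while Hox (-0.23) and cell cycle genes (-0.29) turned without passing. With genes near a pooled-list summit as background, 0 lists were occupied less often (transfer RNA genes -1.79), and Hox (-1.27) and cell cycle genes (-1.17) turned. With the nearest start site only, regulators of mitochondrial and growth genes fell to 0 of 11 (log2 odds 0.080, from 2.87), oxidative phosphorylation to 0 of 91 (-2.92), and germ line genes turned to 0.080. Lists with few occupied genes turn easily, since 0.5 is added to each cell of their odds.

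Against GC-matched peaks, 0 motifs were more and 0 less frequent, and Zelda (-0.43) and core promoter motif 1 (0.47) turned without passing. That alternative removes the GC difference, and TATAAA fell from a log2 odds of 0.66 to 0.069. Among promoter peaks, 2 motifs were less frequent (adding the nuclear receptor motif), and GAGA factor (-0.097) and Zelda (-0.91) turned. With a 50 bp window GAGA factor (-0.74) and NRF1 (-0.51) turned.

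Leaving out a replicate (without replicate 3, then without replicate 4) gave 1.33-fold and 0.61-fold for 5' UTRs, 0.99 and 0.97 for other exons, 0.95 and 0.90 for introns, 1.13 and 1.22 for 2L, 1.06 and 1.00 for 2R, and 0.33 and 0.50 for chromosome 4. It gave 2 and 1 lists occupied more often and 1 and 2 less often, with log2 odds of 2.86 and 2.26 for broadly expressed genes, -1.81 and -3.51 for histones and -1.58 and -0.050 for cell cycle genes. It gave 3 motifs (adding GAGA factor and DRE) and 1 more frequent, and 0 and 1 less frequent, with log2 odds of 0.034 and -0.14 for Zelda, -0.048 and 0.0098 for the E-box, 0.61 and 0.096 for core promoter motif 1, and -0.19 and 0.017 for ETS. No paired analysis was possible because there is 1 group.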

Other observations

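The families and tests in this part were chosen after the gene lists and the mitochondrial map had been seen. Of 52 translation initiation and elongation factor genes, 6 were occupied at the promoter (eEF1alpha1, eEF1gamma, eIF1, eIF3c, eIF4EHP and eIF6; 11.5% against 5.33% of other protein-coding genes, Fisher's exact test, adjusted p = 0.15 over 8 families). Proteasome genes were occupied at 2 of 48 (Rpn3 and Rpn5), aminoacyl-tRNA synthetase genes at 2 of 35 (IleRS and SerRS), vacuolar ATPase genes at 1 of 33 (Vha100-2) and chaperonin CCT genes at 0 of 8, each with an adjusted p of 1. Genes of small nucleolar RNAs (5 of 269, adjusted exact p = 0.15) and small nuclear RNAs (1 of 32, adjusted p = 1) did not pass either. Other non-coding RNA genes were occupied less often than the rest of the genes, 64 of 3261 (1.96%) against 5.07% (adjusted exact p = 2.1e-16). A gene with more annotated start sites has more places to be counted as occupied. The number of start sites was not adjusted for, so this difference does not show avoidance.

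Coverage of the mitochondrial genes was uneven. Peaks covered 96.4% of mt:Cyt-b, 88.7% of mt:ND3, 81.0% of mt:CoII, 64.1% of mt:ATPase6 and 55.7% of mt:ND1, but 46.9% of mt:ND5, 43.8% of mt:ND4 and 12% of mt:ND6. The widest gaps in the coding part were M 9033 to 10432, from mt:ND4 across mt:ND4L to mt:ND6, and M 1 to 1282, over mt:ND2 and its flanking transfer RNA genes.

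The first pattern weighed is these gaps. Reads that match more than 1 place exactly do not account for those in the coding part, since 0.32% of the 36-base words starting in them occur again in the assembly. Near matches were not counted there, and the aligner is not known. The first 821 bp of the control region (M 14917 to 15737) were picked as its longest stretch of 36-base words that occur once. There 9.01% lie within 2 mismatches of another place, just under a limit of 10% set after seeing the data, and no list has a peak. Reads that match more than 1 place are thus argued against in that stretch, but narrowly. In the whole control region 49.7% of the words occur again (49.2% within the mitochondrial genome and 4.77% elsewhere, and 42.8% at 50 bases). This lies between the limits of 10% and 50% set in advance, so lost reads and absent protein cannot be told apart in its repeated part. Peaks were called against a control with settings that are not given, so a missing peak does not by itself show either. Base composition is a candidate explanation for the coding gaps: covered segments had a GC content of 25.9% and uncovered ones 16.5%, a difference of 9.35 points, and for the control region, at 4.28%, it stays open too. Whether low GC content reduced the recovery of DNA in the libraries or marks where the tagged protein bound less was not tested, because no control sample was used here, and no biological explanation was tested.

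The second pattern is the occupancy of cytosolic ribosomal protein promoters. Low promoter GC content was argued against, since these promoters were hardly lower in it than those of other protein-coding genes. Their mean was 41.9% ± 4.92 (SD), against 42.7% ± 4.90. Other genes matched to them on GC content were occupied at 4.88%, not 50%. With such similar GC content, matching could hardly move this share from the 5.05% of all other genes, so it adds little. Whether the occupancy extends to other genes of translation stays open: 11.5% of the translation factor genes were occupied, above 2 times the 5.33% of other genes but without passing the test. Ribosomal protein genes are among the most highly transcribed, and open, active promoters can be recovered in immunoprecipitations whatever the protein. Expression and an untagged line were not analysed here, so that artefact and the hypothesis that the tagged protein itself binds these promoters both stay open, and no biological explanation was tested.

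The third pattern is the set of nuclear peaks and their low GC content. Nuclear copies of mitochondrial sequence, on which mitochondrial reads could be placed, were sought with BLAST at an e-value limit of 1e-05. There were 9 nuclear matches, the longest 601 bp, and 0 of the 1268 nuclear thresholded peaks (0%) overlapped any of them. With 9 matches this share had to be low wherever the reads were placed, so the share itself tests little. It shows only that no nuclear thresholded peak lay on a match found here. Neither the location of the peaks nor 1 replicate alone accounted for the GC difference from remaining regions with background included. This was 4.997 points within promoters and 4.92 outside them. For the 1268 highest nuclear peaks of each replicate it was 4.49 points in replicate 3 and 6.87 in replicate 4. No such split was made against regions with a q-value of 0.05 or less. Background in the comparison list is a candidate explanation for most of the GC difference. It was 4.99 points from all remaining pooled regions and 1.04 from those with a q-value of 0.05 or less. Those are also the stronger of the remaining regions. A GC content that falls as the signal rises would give the same, and the comparison cannot tell these readings apart. A preference of the tagged protein for A+T-rich DNA and a GC bias of the libraries or of the control both remain open. Promoters of low GC content were occupied less often, not more. The 1407 genes with the lowest promoter GC content (mean 34.0%) were occupied at 2.99% (95% Wilson interval 2.22 to 4.01). Of the 12446 others outside the ribosomal list, 5.29% were (4.91 to 5.69). Lower recovery of such DNA could give this, and the number of start sites was not adjusted for, so these shares decide neither. On the mitochondrial genome peaks lay on segments of higher GC content. Lower recovery of DNA of low GC content stays a candidate there, so this does not argue against a GC bias.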
